A study of Oryza sativa Indica Group with 24 samples.

How the data were processed

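Leaves of rice (Oryza sativa, Indica Group, cultivar Nagina 22) were compared on spotted complementary DNA arrays with 2 colours. Per the labels, each array held control RNA from plots irrigated to 100% of field capacity in the first channel (Alexa 488) and RNA of the same age from a stressed plot in the second channel (Alexa 594). Field capacity is the water a soil holds after it has drained, and it was set to 60% for mild, 40% for moderate and 15% for severe stress. The series holds 24 arrays, 1 for each of 3 stress levels on each of 8 days after germination. All arrays had the same dye orientation, so a dye bias that is constant over arrays stays in every ratio of stress over control and cancels in the differences between levels and between stages. Per the labels' protocols, several leaves per plot made up a sample; each array is labelled as leaves, although the protocol for RNA extraction names panicles too. Arrays of a level share a plot code in the labels, so the p-values given here measure the spread between days and arrays of such plots, not between plots.

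For 21 arrays the deposited file is the output of the QuantArray software, which gives the raw intensity and local background of each spot and channel on a linear scale, per the file headers. For 2 arrays of day 75 (mild and moderate) the deposited file is a short table with the same intensity columns and a log2 value. No scanner file of the severe array of day 75 was used here. The headers speak of background subtraction. That holds for the ratios in the files' first block, and the intensity columns used here still contained the background. The intensities of the mild array of day 45 reached 5242800, which is 80 times the 65535 reached on the other arrays. Its spots covered 8000 square micrometres of pixels 10 micrometres wide, which makes 80 pixels, so that the file holds sums over pixels. It was used as deposited, and an alternative divided it by 80.

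A value table deposited by the authors holds a log2 ratio per spot for all 24 arrays. In it, the mean of each spot over the 8 days of a level lay within 0.00375 of 0, so these values had been centred per spot within each level and hold only differences between days. After centring the scanner log2 ratios in the same way, 21 columns matched their own array best, with correlations across clones from 0.66 to 0.95 and slopes from 0.58 to 1.08, which places the table on the log2 scale with stress over control as its direction. The column medians ran from -0.18 to 0.09. The normalization before centring is not given in the sources used here. The moderate columns of days 52 and 55 each matched the other day's scanner file, and were not exchanged. Spot positions of the table were matched to clone names through the scanner files, over print rows 1 to 10 only, since the layout of 1 file differed in the last print rows; 6480 clones could be used. The values of the 2 short tables were the same as their columns of the value table, within 0.006 at all 15532 spots.

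Each array has 15552 spots in 48 print blocks: 14592 spots of 7296 clones printed in duplicate, 144 control spots and 816 empty spots. The files used here do not pair the clone names with genes, and none of the 7296 names occurred in a reference table of 39387 rice genes, so that clones are given by the name printed in the files and no gene list could be tested. The mild file of day 75 was joined by clone name and the moderate file of day 75 by spot position.

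The background was corrected with normexp (offset 50), each array was normalized with 1 loess curve over all its clone spots (span 0.3, 4 iterations), with control, empty and ignored spots at weight 0, spots marked to be ignored by the scanner software were left out, and duplicate spots were averaged. No scaling between arrays was applied. A filter asked that a clone lie above its background by 2 background SDs in at least 1 channel on a share of at least 0.5 of the arrays; all 7296 clones passed. Signal above the array's own empty spots was much rarer: the median over arrays was 37.6% of clone spots above the 95th percentile of the empty spots in the control channel and 36.6% in the stress channel. The number of arrays limits the precision.

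All tests used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the log2 ratios, with Benjamini-Hochberg adjustment and a threshold of 0.05; tables were read with the data.table package (version 1.17.8) and plots drawn with Python 3.11.15 and matplotlib 3.10.9. Each level was tested against 0 over its days, with 1 spread for all levels. The mean of the 3 levels against 0 used the day as a random block (within-day correlation 0.25). Differences between levels and the slope on field capacity used the day as a fixed factor. Late days (63, 67, 71 and 75) were set against vegetative days (45 and 52, as the labels name them) with the level as a factor and the day as a random block, and the interaction asked whether that difference itself differed between severe and mild stress. These designs, the alternatives and the rule for names were fixed before the data were examined. The day pairs the arrays of different levels in the labels; deviations of arrays of the same day from each clone's mean correlated at 0.35 on average over day pairs, against -0.07 between days. For correlations between levels, the value without lasting change came from 99 draws in which the sign of all arrays of a day was turned at random.

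The rule for names took, per comparison with calls, at most 2 clones that were higher and 2 that were lower: those with the largest log2 values past the threshold and, for a single level, with the same sign on all but at most 1 of its arrays. The limit of 2 is the rule's own for files without gene names. Its part for comparisons with fewer than 5 calls, to give the clones with the highest and lowest moderated t, was left out after the data had been seen, so no clone is named for comparisons without calls. Alternatives were no background correction, print-tip loess, median centring, scaling between arrays, no dim filter, ignored spots kept, the value table, array weights, leaving out each day, the day of quantification as a block, other uses of the day block and a slope over days. Further alternatives were added after the data had been seen. The files' quantification days fall into 2 sessions, days 45 to 55 (9 arrays) and days 59 to 71 (12 arrays), with no session in the files of day 75.

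The procedures were tested on simulated log2 ratios for 7296 clones, with each clone's estimated spread and 1 within-day correlation for all. The noise was drawn with the same spread on every array and independently for each clone. The SD of the real arrays ran from 0.24 to 1.40, so recovery in the real data may differ. Of 100 clones changed by 1 on the log2 scale, the test recovered 77 for severe stress against control, 96 for the mean of the 3 levels, 48 for severe minus mild, 13 for late minus vegetative and 0 for the interaction. Of 100 clones changed by 0.5, it recovered 15, 57, 1, 0 and 0 in the same order.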

Results

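The series followed gene expression in rice leaves under drought in the field, at 3 levels of irrigation and at 8 ages, each on 1 array against well-watered plants of the same age. Ratios from 23 arrays entered the comparisons: 8 of mild, 8 of moderate and 7 of severe stress. Days 45 and 52 after germination were vegetative, day 55 lay before flowering, and days 63 to 75 covered the time after flowering and seed setting; no stage is named for day 59. The stress had lasted from 7 to 37 days. Duplicate spots of a clone correlated within an array at 0.73 to 0.97 (median 0.89). The SD of the log2 ratios ranged from 0.24 on the mild array of day 63 to 1.40 on the severe array of day 71. The share of clone spots brighter than the 95th percentile of the empty spots ranged from 7.37% to 58.5% in the control channel and from 8.44% to 65.6% in the stress channel, so that many clones were measured close to the level of empty spots.

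The number of clones that differed between stress and control changed with age and level. Under mild stress 33.1% of clones had a ratio of 2-fold or more on day 45, 20.3% on day 52 and 17.7% on day 55, and the share fell to 0.754% on day 63 before it stood at 17.4% on day 71. Under severe stress the share was 8.52% on day 45, 13.7% on day 52, 2.67% on day 59 and 23.7% on day 71. Under moderate stress the highest share was 10.3%, on day 55, followed by 7.71% on day 52. Averaged over days, the shares were 14.0% ± 10.2 (SD, n = 8) for mild, 5.16% ± 3.04 (SD, n = 8) for moderate and 9.94% ± 6.90 (SD, n = 7) for severe stress. The profile over age depended on the normalization. With median centring in place of loess, day 59 rose to 17.4% under mild, 15.1% under moderate and 9.97% under severe stress, and day 63 under severe stress from 6.44% to 18.8%; the means for mild, moderate and severe stress were 16.3%, 7.63% and 15.0%. Without background correction the means were 7.54%, 3.24% and 5.40%. In the value table, which is another quantity, since a value there is a deviation from the mean of its level, they were 9.06%, 6.40% and 15.1%. On day 71 clones with lower signal in the stressed leaves prevailed: 19.5% were lower and 4.25% higher by 2-fold or more under severe stress, and 15.0% and 2.45% under mild stress. On day 59 the balance was the opposite under mild stress, with 7.03% higher and 2.04% lower. There was 1 array per level and day, so these shares have no replicate check. The mild array of day 45 had been quantified as sums over pixels. Divided by the 80 pixels of a spot, its share was 27.2%. On that array as deposited, clones whose names start with MK, printed in print rows 9 to 12, had a median log2 ratio of -1.22. The median clone of this set thus counted as 2-fold lower. Under mild stress the same median was -0.701 on day 71, and 0.301 and 0.427 on days 52 and 55. The shares were not computed with print-tip loess. How far a shift of a set or of print rows made up the shares was not tested.

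**Figure D1:**
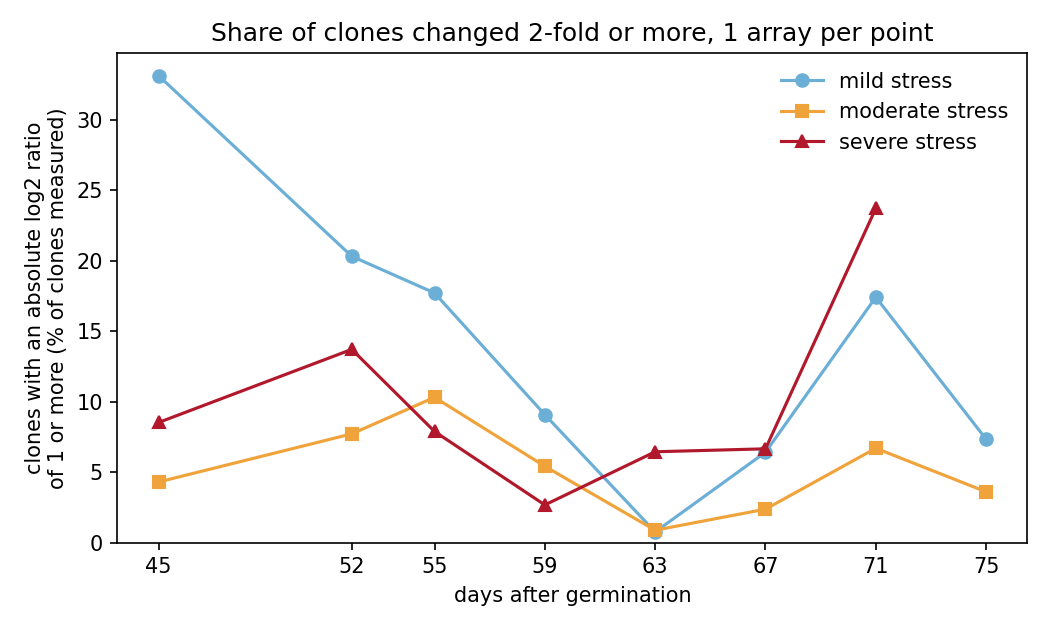
Share of clones with an absolute log2 ratio of 1 or more on each array, in percent of the clones measured, against days after germination, with 1 line per stress level and 1 array per point. Shares were lowest on day 63 for mild (0.754%) and moderate stress (0.877%), and the highest were those of mild stress on day 45 (33.1%) and severe stress on day 71 (23.7%).

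Arrays of different levels on the same day resembled each other more than arrays of different days. Across clones, the Pearson correlation of log2 ratios averaged 0.45 over the 22 pairs of the same day (Spearman 0.40), 0.12 over the 77 pairs of the same level on different days (Spearman 0.11) and 0.12 over the 154 pairs that shared neither. By their mean, same-day correlations were highest on day 71, from 0.70 to 0.83, followed by day 55, from 0.60 to 0.62, and day 59, from 0.51 to 0.59. Day 67 ran from 0.25 to 0.68. The mean was lowest on day 52, where mild and moderate correlated at 0.025. Between days 4 pairs fell below -0.3: mild day 55 with moderate day 59 (-0.36), mild day 55 with moderate day 63 (-0.34), moderate day 52 with severe day 63 (-0.35) and moderate day 55 with severe day 59 (-0.31). The dyes are stated in the labels and the ages could differ in direction, so the direction of the ratios was kept. Clones are not independent replicates, so no p-value is attached to these correlations.

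**Figure D2:**
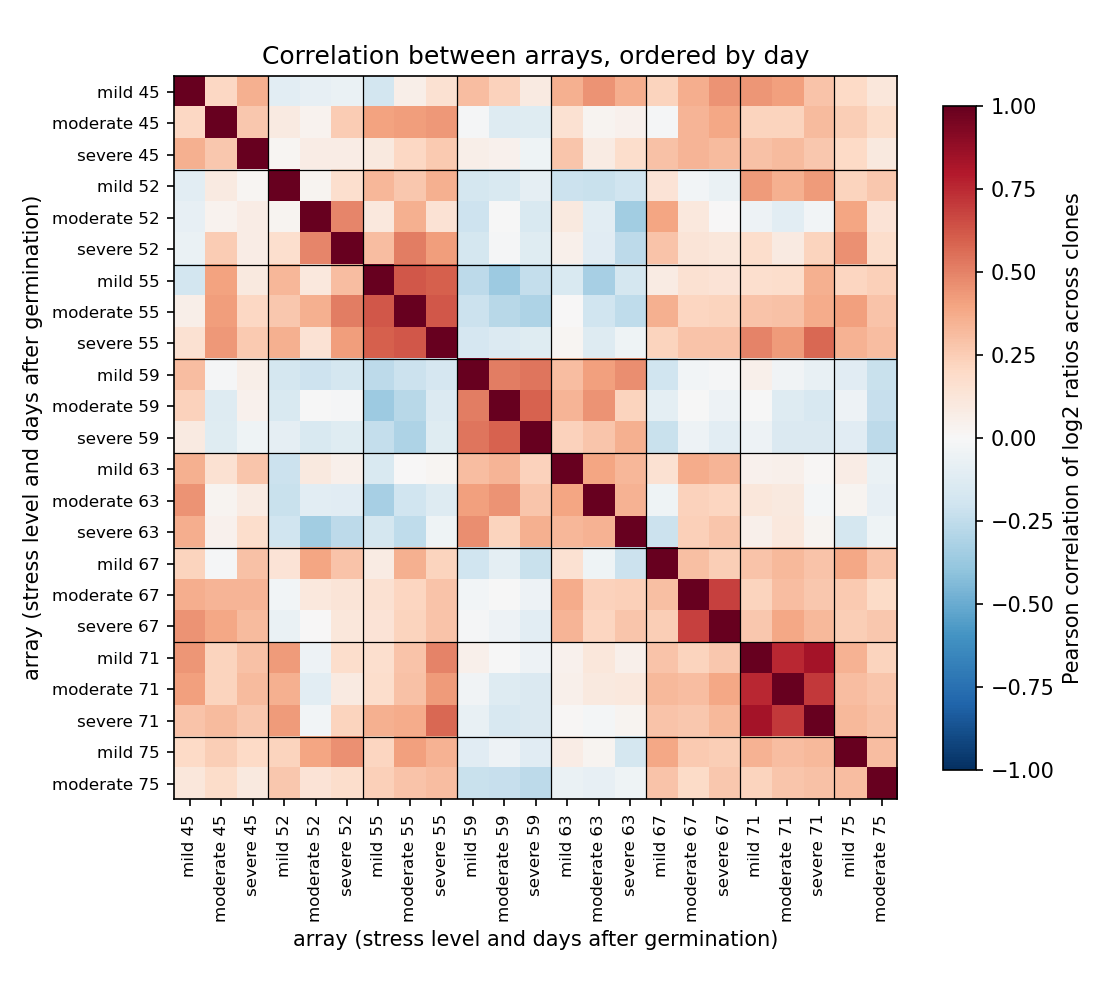
Pearson correlation of log2 ratios across clones between all pairs of the 23 arrays, ordered by days after germination, with black lines between days and the colour running from -1 to 1. The highest values lie in blocks along the diagonal, pairs of the same day, up to 0.83 on day 71. Other such blocks hold lower values, down to 0.025 on day 52, while pairs of different days reach 0.58.

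Severe stress was set against control over its 7 days. In severely stressed leaves 1 clone was higher and 15 were lower than in control leaves. The higher clone, NL26_D10, had 1.94-fold the control signal (log2 ratio 0.96 ± 0.38, SD, n = 7, adjusted p = 0.022), and lay above 0 on 7 of 7 arrays. Of the lower clones, MK_PG6_B09 had a log2 ratio of -1.36 ± 0.82 (SD, n = 7, adjusted p = 0.0159) and NL10_E02 of -1.16 ± 0.60 (SD, n = 7, adjusted p = 0.0352); both lay below 0 on 7 of 7 arrays. The adjusted p-values rest on 1 spread for all levels, not on the SD of the severe arrays given beside them. For MK_PG6_B09 the SE was 0.224, its SD under moderate stress was 0.325, and its severe array of day 71 lay at -3.01. NL26_D10 was printed in print row 3, NL10_E02 in row 1 and MK_PG6_B09 in row 12. MK_PG6_B09 is a dim clone, not among the 2982 that lay above the empty spots on a share of at least 0.5 of the arrays. Its log2 ratio was -0.71 (adjusted p = 0.00948) without background correction and -0.51 (adjusted p = 0.178) with print-tip loess. NL10_E02 did not pass without background correction (-0.93, adjusted p = 0.138), with print-tip loess (-0.73, adjusted p = 0.125), with median centring (-0.98, adjusted p = 0.266) or with scaling between arrays (-1.10, adjusted p = 0.0672), and passed in 10 of 24 settings in all. NL26_D10 passed in 18 of 24 and missed the threshold with median centring (adjusted p = 0.0555), without day 55, 63 or 67 (adjusted p from 0.0702 to 0.13) and within the first and second quantification sessions (adjusted p = 0.444 and 0.0577). In the other levels, which were not called, the means of NL26_D10 were 0.12 under mild and 0.29 under moderate stress, those of MK_PG6_B09 were -0.64 and -0.21, and those of NL10_E02 were -0.24 and -0.70. The limma test called 16 of 7296 clones in all, and 1195 clones had an unadjusted p under 0.05, which is 16.4%. The count was 64 with the day as a random block, 48 with print-tip loess, 85 with array weights and 2 over clones above the empty spots. It was 0 without day 55 or without day 67, 1 without day 63, 3 without day 71 (and 3 without its severe array alone), 8 without day 75, 26 without day 52, 131 without day 59 and 80 without the mild array of day 45; within the first quantification session 0 clones were called and within the second 48 (29 higher and 19 lower), of which 2 were among the 16.

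Under mild and moderate stress no clone passed the test. For mild stress the limma test called 0 clones, with 1648 at an unadjusted p under 0.05 (733 higher and 915 lower, 22.6% of all clones) and a smallest adjusted p of 0.0662. The same count was 56 with the day as a random block, 10 higher and 46 lower, 73 without background correction, 99 without day 59 and 234 without the severe array of day 71, which shares the estimate of the spread. For moderate stress it called 0 clones, with 488 at an unadjusted p under 0.05 (6.69%) and a smallest adjusted p of 0.411; array weights gave 33.

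The mean of the 3 levels asked which clones differed from control on average over the levels. It does not ask for a change at each level. Over all levels 137 clones were higher and 351 lower in stressed leaves. Among the 2982 clones above the empty spots, 15 were higher and 151 lower, and within the first quantification session 3 were higher and 204 lower. The called clones that were higher had a median log2 ratio of 0.43 under mild, 0.37 under moderate and 0.40 under severe stress. Those that were lower had medians of -0.80, -0.48 and -0.91. Both sets were chosen by the mean of the same arrays. Medians of the same sign at every level thus follow largely from the choice and are no separate evidence for each level. The 2 highest were NL9_F09, with a log2 ratio of 0.76 (SE 0.23, adjusted p = 0.049), above 0 on 18 of 23 arrays, and NL19_A08, with 0.67 (SE 0.15, adjusted p = 0.0146), above 0 on 20 of 23. The 2 lowest were MK_PG8_H07, with -1.42 (SE 0.27, adjusted p = 0.008), below 0 on 21 of 23 arrays, and MK_PG9_C01, with -1.37 (SE 0.30, adjusted p = 0.0128), below 0 on 20 of 23. NL9_F09 and NL19_A08 were printed in print rows 2 and 1, and MK_PG8_H07 and MK_PG9_C01 in rows 12 and 11, near opposite ends of the array. NL9_F09 stood highest on day 59, at 2.23, 2.94 and 2.52 under mild, moderate and severe stress; without that day its log2 ratio was 0.49 (adjusted p = 0.111). With print-tip loess none of these 4 clones passed the threshold: NL9_F09 was at 0.62 (adjusted p = 0.173), NL19_A08 at 0.57 (adjusted p = 0.056), MK_PG8_H07 at -0.60 (adjusted p = 0.076) and MK_PG9_C01 at -0.66 (adjusted p = 0.0706). Day 71 showed the lower set most strongly, with a median log2 ratio of -1.60, and day 59 not at all, at 0.016. The arrays of both days took part in the choice of the set.

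Clone sets took unequal parts in these calls. Clones whose names start with MK supplied 113 of the lower calls and 0 of the higher ones, out of 1152 clones; those that start with NL_ supplied 127 and 4, out of 1536; the remaining NL clones supplied 111 and 133, out of 4608. The sets were printed in print rows 9 to 12 (MK), 7 to 10 (NL_) and 1 to 8 (NL), so that NL and NL_ shared rows 7 and 8, and NL_ and MK rows 9 and 10. With rows taken in pairs, the lower calls within NL_ and MK were more frequent further down the array. Among NL_ clones they were 10 of 576 in rows 7 and 8 and 117 of 960 in rows 9 and 10. Among MK clones they were 18 of 336 in rows 9 and 10 and 95 of 816 in rows 11 and 12. For single rows of MK the order broke, with 8.93% in row 10 and 6.37% in row 11. Among NL clones the lower calls were 30 of 1296 in rows 1 and 2 (2.31%) and 22 of 720 in rows 7 and 8. Of 648 NL clones per row, 51, 25, 5, 10, 39 and 3 were called higher in rows 1 to 6, which is no steady fall. In rows 7 and 8 the higher calls were 0 of 360 each. The median log2 ratio of NL clones went from 0.18 in row 1 to -0.061 in row 8. In rows 9 and 10 the share was 5.36% for MK and 12.2% for NL_ clones, and in rows 7 and 8 it was 1.74% for NL_ and 3.06% for NL clones. The limma test of the mean called 488 of 7296 clones, with 1923 at an unadjusted p under 0.05. With print-tip loess, which fits each print block on its own, it called 106, of which 66 were among the 488. With the quantification session as a block it called 303. That fit leaves out day 75, which has no session. Without day 75 and with no session fitted the count was 171. Within the first session it called 207 and within the second 0. At an unadjusted p under 0.05 the limma test had 1380 clones in the second session and 1156 in the first. The smallest adjusted p of the second was 0.0727, so its 0 calls do not show that the change was absent there. Without a day block the count was 1475. It was 85 without day 45 (309 without its mild array alone), 145 without day 55, 1025 without day 59, 56 without day 67, and 211 without day 71.

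**Figure D3:**
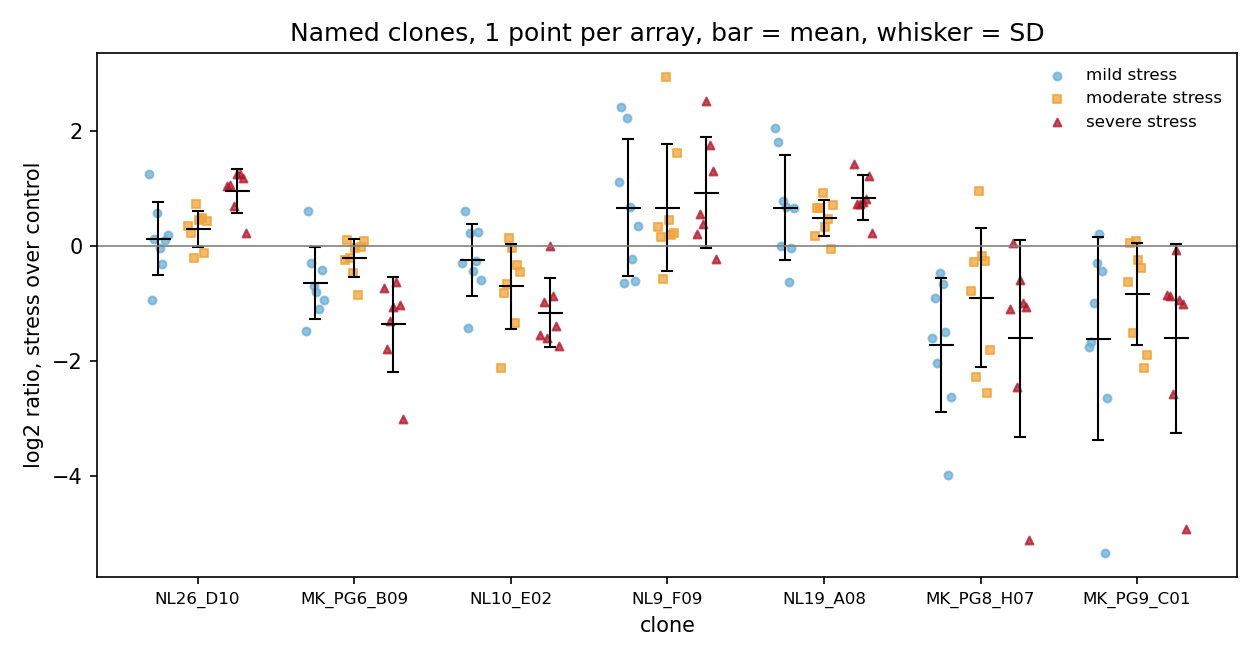
Log2 ratio of stress over control of the 7 named clones, 1 point per array, by stress level, with the mean as a bar and the SD as whiskers (8 mild, 8 moderate and 7 severe arrays). NL26_D10 lies above 0 and MK_PG6_B09 and NL10_E02 lie below 0 on all 7 severe arrays, and the ratios of MK_PG8_H07 and MK_PG9_C01 spread down to -5.10 and -5.34.

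The 3 levels resembled each other in their mean ratios. Across clones the mean log2 ratios correlated at 0.67 between mild and moderate (Spearman 0.65), 0.76 between mild and severe (0.66) and 0.68 between moderate and severe (0.63). Levels of the same day may share control RNA and share the age of the plants, and turning the sign of whole days at random gave mean correlations of 0.35, 0.44 and 0.43, with highest values of 0.66, 0.74 and 0.74. The covariances were 0.0572, 0.107 and 0.0592, against 0.0165, 0.0341 and 0.0214 with turned days. With disjoint days for the 2 levels, which share no control array, the correlations were 0.28 and 0.45 for mild and moderate, 0.37 and 0.46 for mild and severe, and 0.46 and 0.23 for moderate and severe. Part of any excess may come from the dye orientation common to all arrays. No call was shared between levels, since only severe stress had any.

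The levels were then compared with each other, to ask whether expression followed the depth of the drought. A dye bias or control RNA common to a day cancels here. No clone passed the test between moderate and mild, between severe and mild or between severe and moderate stress. The limma test called 0 of 7296 clones in each, with 437, 386 and 368 at an unadjusted p under 0.05, or 5.99%, 5.29% and 5.04%. The slope on field capacity called 0 clones as well, with 389 at an unadjusted p under 0.05 and a smallest adjusted p of 0.382. The median SE of a log2 difference was 0.22 to 0.24, so that small differences were not detectable with these arrays. On simulated ratios the test of severe minus mild recovered 48 of 100 clones changed by 1 on the log2 scale and 1 of 100 changed by 0.5. Differences of 2-fold could thus be missed too. Within the second quantification session, 1 clone was called for severe minus mild and 1 for the slope; within the first, 0. Without day 52, 1 clone was called in each of these, too.

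Late and vegetative days were compared to ask whether the response to drought changed with the stage. No clone passed the test. The limma test of late minus vegetative called 0 clones, with 93 at an unadjusted p under 0.05, or 1.27%, and a median SE of 0.31. That share lies below the 0.05 expected without any change. On simulated ratios this test recovered 13 of 100 clones changed by 1 on the log2 scale. Its 0 calls thus do not show that the response was the same at both stages. The interaction, whether that difference itself differed between severe and mild stress, called 0 clones, with 962 at an unadjusted p under 0.05, or 13.2%, and a smallest adjusted p of 0.0987. The median SE of the interaction was 0.563, and on simulated ratios it recovered 0 of 100 clones changed by 1. Its 0 calls thus decide nothing about changes of that size. It called 3 clones without day 71. Leaving out day 45 or day 52 keeps 1 vegetative array per level. Leaving out the mild array of day 45 alone keeps 1 vegetative array under mild stress. Those fits called clones, but they rest on single arrays. Their counts decide nothing about the interaction and are listed only with the other settings below. The vegetative days were all quantified in the first session, and days 63 to 71 in the second, so stage and quantification session cannot be told apart.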

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

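The SD of log2 ratios on the severe array of day 71 was 1.40, far from the other severe arrays, of which the next was at 0.70 (n = 7). It was the only value set apart in this way among 30 groups of array values tested, where chance alone sets apart about 1 in 20.

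The severe column of day 75 in the value table has no scanner file here and entered no comparison of the report. In it 26.2% of clones lay 2-fold or more from their mean over the severe days, against 1.59% (moderate day 45) to 39.2% (severe day 71) in the other columns.

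Control spots entered no comparison. The spots named uYIR3 had a mean log2 ratio of -3.02 (SD 0.67 over 23 arrays) and lay below 0 on 23 of 23, against -0.17 (SD 0.47) for the empty spots; rYIR07 was at -2.83, also below 0 on 23 of 23. Not all control spots went this way: rYIR08 was at 1.76, above 0 on 21 of 22 arrays, and rYIR04 at 0.543, above 0 on 18 of 22. What the control spots hold is not given in the sources used here.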

How the results depend on the processing

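Alternatives that concern mild day 45 in pixels, empty spots, single arrays, print rows and single quantification sessions were added after the data had been seen. Counts of called clones for moderate minus mild, severe minus moderate and late minus vegetative stayed at 0 under every alternative run. The 16 calls of severe stress became 2 without background correction, 48 with print-tip loess, 9 with median centring, 5 with scaling between arrays (1 higher and 4 lower), 85 with array weights, 64 with a replicate block (the day as a random block), 2 over clones above the empty spots, 3 without the severe array of day 71, 80 without the mild array of day 45, 7 over print rows 1 to 10, and 0 and 48 within the first and second quantification sessions. The 488 calls of the mean became 106 (17 higher and 89 lower) with print-tip loess, 248 with median centring, 303 with the session as a block (which leaves out day 75; 171 without day 75 and no such block), 1475 without the day block, 166 (15 higher and 151 lower) over clones above the empty spots, 309 without the mild array of day 45, and 207 and 0 within the sessions. For mild stress 0 became 73 without background correction, 4 with print-tip loess, 56 with the day block, 234 without the severe array of day 71 and 2 within the first session. For moderate stress 0 became 1 with print-tip loess, 4 with scaling and 33 with array weights. For severe minus mild and for the slope 0 became 1 with array weights and 1 within the second session. For the interaction 0 became 119 without the mild array of day 45. Leaving out each day gave 0 (without day 45, for example) to 99 (without day 59) for mild, 0 (without days 55 and 67) to 131 (without day 59) for severe stress, 56 (without day 67) to 1025 (without day 59) for the mean, 0 to 1 (without day 52) for severe minus mild and for the slope, and 0 to 497 (without day 52) for the interaction; for moderate stress it gave 0 throughout. The cause of these shifts was not tested, except that single sessions, single days and fewer clones reduce what was fitted. For the interaction, the fits without day 45 or day 52 keep 1 vegetative array per level. The fit without the mild array of day 45 keeps 1 under mild stress. The interaction counts of these fits rest on single arrays and decide nothing about the interaction. The day block changed no other call. The filter on dim clones removed none, so leaving it out tests nothing. The value table is centred within levels and gave values for the stage comparisons alone, and gene lists could not be run. The session lies within the day factor of the level differences, so it gives no further block there. The 7 named clones kept their sign under all settings run, and passed the threshold in 18 of 24 settings for NL26_D10 (log2 values of 0.79 to 1.08), 17 of 22 for MK_PG6_B09 (-1.48 to -0.51), 10 of 24 for NL10_E02 (-1.37 to -0.73), 10 of 24 for NL9_F09 (0.44 to 0.94), 20 of 24 for NL19_A08 (0.46 to 0.92), 21 of 23 for MK_PG8_H07 (-1.62 to -0.60) and 21 of 23 for MK_PG9_C01 (-1.56 to -0.66). The named clones were chosen as the most extreme calls on the same arrays, so their kept sign is no separate check. The settings counted for them include the one without the dim filter, which repeats the main fit and could not fail. The median share of clones changed 2-fold per array, 7.33%, was 9.97% with median centring, 5.00% without background correction and 6.99% in the value table, where it refers to the mean of a level. The clones above the empty spots are the 2982 that lay above them on a share of at least 0.5 of the arrays.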

Other observations

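Tests of day sharing by spots, channels and print blocks, of the dye bias by level and day, of the clone sets by print row, of the exchanged columns and of the shares between levels were chosen after the results had been seen; the counts over other splits and the test of the calls with print-tip loess were set out before. Each day was also tested alone, on 3 arrays (2 on day 75) and without a day block. Without a day block the mean over all days called 1475 clones, more than any single day. The 488 rest on a day block, so they are not comparable with the counts of single days. With the 3 levels of a day as repeats, which share a day and perhaps control RNA, so that their p-values are too small for a day as such, limma called 1362 clones on day 71 (197 higher and 1165 lower), 853 on day 45 (363 and 490), 715 on day 55 (97 and 618), 324 on day 52 (79 and 245), 148 on day 59 (110 and 38), 106 on day 67 (6 and 100) and 0 on days 63 and 75. Mild stress changed a larger share of clones 2-fold than moderate stress, by 8.85 points (SD 9.06 over 8 days, higher on 7 of 8; exact two-sided sign-flip p = 0.0156, adjusted over 3 comparisons 0.0469). The gap was 8.11 points (adjusted p = 0.0469) with mild day 45 divided by pixels, 4.30 points (adjusted p = 0.0234) without background correction, 8.64 points (adjusted p = 0.0703) with median centring and 2.67 points (adjusted p = 0.117) in the value table. Its moderate columns of days 52 and 55, which are likely exchanged, were paired as deposited. An exchange would leave the gap and could change its p-value. Without day 45 it was 6.00 points, without day 63 10.1 points (adjusted p = 0.0469), and without another single day 8.32 to 9.59 points. The adjusted p was 0.0938 without any single day but 63, the lowest that 7 days with the reversal of day 63 can give, so this says nothing about the single days. The call depends on the normalization. The shares were not computed with print-tip loess, so a shift of a clone set or of print rows on single arrays was not tested as its cause. Mild and severe differed by 5.02 points over 7 days (exact p = 0.234, adjusted 0.234), and severe and moderate by 4.56 points (exact p = 0.0938, adjusted 0.141).

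Other splits of the same arrays bear on each count. For the mean of the 3 levels, 1 of 100 patterns of signs turned by day, the real one, gave as many as 488 clones (highest other 191). For severe stress 2 of 100 gave 16 or more (highest other 21). Both shares lie under 0.05, without adjustment for the number of such tests. Chance of this kind is thus argued against for the mean. For severe stress another pattern called more clones than the real one, so chance is not excluded there. For mild and moderate stress, for the 3 differences between levels and for the slope, the real count was 0. Any split gives at least 0, so that 100 of 100 splits gave as many by necessity and nothing follows about chance; the highest others were 377 for mild stress, 0 for moderate stress, 1, 0 and 5 for moderate minus mild, severe minus mild and severe minus moderate and 0 for the slope. The 377 clones were called with days 52, 55, 67 and 75 turned against days 45, 59, 63 and 71. This pattern cuts across both quantification sessions. It was picked as the highest of the turned patterns and was not tested on its own. Under mild stress the median log2 ratio of MK clones was -1.22, -0.45, -0.177 and -0.701 on days 45, 59, 63 and 71. It was 0.301, 0.427, -0.0221 and -0.102 on days 52, 55, 67 and 75. Whether this shift gave the calls was not tested. For late minus vegetative and for the interaction there are 15 choices of days, too few for a share under 0.05; the real counts were 0 and the highest others 4 and 15, and 15 of 15 gave as many, again by necessity.

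Arrays of the same day shared their log2 ratios. An F test for day over the 3 levels called 1562 clones, and in 1 of 100 assignments of the arrays of a level to days, the real one, as many were called (highest other 829). Local background shared by a day is argued against by the empty spots, whose correlation within days exceeded that between days by 0.00672, against 0.414 for the clones; for the clones it grew from 0.152 among the dimmest 1824 clones to 0.509 among the brightest 1824. Slide position shared by a day, as far as print blocks capture it, is argued against as the whole cause: after print-tip loess the excess was 0.409, and above 0 on 8 of 8 days (mean 0.385, SD 0.248, exact two-sided sign-flip p = 0.00781); positions within a block were not tested. Control RNA shared by the arrays of a day may add to it: the part of the within-day covariance that runs through the stress channel averaged 0.103 (SD 0.134 over 8 days, exact two-sided sign-flip p = 0.0859), where shared control RNA alone predicts 0, and the part through the control channel averaged 0.0134 (SD 0.065, exact p = 0.609). The stress channel part was above 0 on 6 of 8 days and the control channel part on 7 of 8. Day 55 had 0.285 and -0.138 in the same order. With 8 days the part of shared control RNA cannot be told apart from that of the stress channel. Labelling, hybridization or scanning of a day cannot be told apart from the plants' response at that age, since the control spots shared their deviations within days too (excess 0.212) and the sources used here do not give how the arrays of a day were handled beyond the quantification sessions; a response to drought that depends on age stays open as well.

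Position on the slide is a candidate explanation for part of the 488 calls of the mean of the 3 levels. With print-tip loess 66 of them were called in the same direction; 477 of the 488 kept their sign, but their median absolute log2 ratio went from 0.589 (median SE 0.153) to 0.319 (median SE 0.118). The calls thus ended with smaller ratios at a smaller SE, and part of that decrease is expected because the clones were chosen for their ratios in the first fit. A difference between the clone sets alone is argued against as the whole cause: NL_ clones had a lower median log2 ratio in print rows 9 and 10 than in rows 7 and 8, by -0.153 (SD 0.0782 over 8 days, below 0 on 8 of 8; exact two-sided sign-flip p = 0.00781, adjusted over 5 differences 0.0391). These rows were compared after the calls by row had been seen on the same arrays, so the p-value is no separate check. For NL clones the difference between rows 7 and 8 and rows 1 and 2 was -0.173 (SD 0.216, adjusted p = 0.117). For MK clones the difference between rows 11 and 12 and rows 9 and 10 was -0.201 (SD 0.236, adjusted p = 0.117). Within shared rows MK minus NL_ was 0.139 (SD 0.226, adjusted p = 0.137) and NL_ minus NL 0.015 (SD 0.11, adjusted p = 0.734). Different clones lie in different rows, so clones of unlike response stay open beside position. A constant dye bias alone predicts the same ratio on every day. The median of the 488 clones, in the direction of their change, went from 0.0482 on day 59 to 0.99 on day 71 (F for day 9.87, permutation p = 0.001 over 1000 assignments of arrays to days). The lower calls had a median of 0.0161 on day 59 and -1.60 on day 71. A constant bias alone does not give such values. Clones in general shared deviations within a day, however, so this does not tell whether a constant bias moved the mean away from 0. A constant dye bias as a part of the change stays open: it adds no difference between severe and mild stress, and over the called clones, in the direction of their change, that difference averaged 0.0336 (SD 0.18 over 7 days, exact two-sided p = 0.625), which decides nothing without arrays of the opposite dye orientation. A response to drought common to the 3 levels remains a hypothesis beside these.

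The moderate columns of days 52 and 55 in the value table are likely exchanged. Their correlation with the scanner values of the other day exceeded that with their own day by 0.733 on average (0.839 against 0.105). An exchange of the scanner files instead is argued against by averages over few pairs. The scanner values of the 2 moderate arrays correlated with the other levels of their own day better than with those of the other day, by 0.179 (0.438 against 0.259). The columns did so the other way round (0.133 against 0.323). Among the scanner values, moderate day 52 went against the average with mild stress, at 0.025 for day 52 and 0.107 for day 55. Both other arrays of day 52 correlated better with moderate day 55 than with moderate day 52. The values were 0.272 against 0.025 for mild and 0.515 against 0.488 for severe stress. Both other arrays of day 55 went with their own day, at 0.619 against 0.107 and 0.622 against 0.144. Seen this way, the average rests on the arrays of day 55.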
